A study of Mus musculus with 4 samples.

How the data were processed

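RNA of E13 hepatoblasts (n = 2) and of hepatocytes from mice 8 weeks old (n = 2) had been hybridised to 4 one-colour Agilent whole-genome mouse arrays, all on 1 slide with 1 scan time per the file headers. Each array held 43379 non-control spots for 41174 distinct probes and 30038 gene names. Per the file headers, Agilent Feature Extraction 10.7.3.1 made the intensity values of each scan by subtracting local background and detrending within the array, with surrogate values for spots not above background and no scaling between arrays. The deposited log2 values of the authors' processed table were the log2 of these intensities minus the array's 75th percentile, as their correlation with the log2 processed signal on each array (Pearson r = 1) and a constant difference showed. The steps themselves were not given in the sources used here. Samples were grouped by the cell type given in the labels, and the comparison, the 31 gene lists and the alternatives planned for each result were set before the data were examined.

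The analysis used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Processed signals were averaged over replicate spots of a probe on the log2 scale, and the array's 75th percentile over all probes was subtracted. The 1639 control spots were left out, and so were 18 probes with a value marked as an outlier. A probe was tested if it was well above background, by the scanner software's own mark, on both arrays of at least 1 group, and a gene was represented by its brightest tested probe, which gave 16421 genes. Group means were compared by the moderated statistics of limma (lmFit and eBayes, 2 residual and 2.5 prior degrees of freedom), and a gene was called where the Benjamini-Hochberg adjusted p was under 0.05. The median standard error of a log2 fold was 0.18. The p-values measure only the spread between these samples, since the labels do not say that they came from separate animals, and the number of arrays limits the precision.

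Where a called gene was not well above background on either array of 1 group, its difference is given as a bound, "at least N-fold". The bound is the mean of the higher group minus the mean, over the arrays of the lower group, of the larger of the gene's value and the lowest value well above background on that array. Where this was 0 or below, no fold is given for a called gene. Uncalled genes and values under the alternatives are fitted log2 folds unless marked as a bound, also where 1 group was not well above background. Only the medians given with bounded genes at their bounds count genes without a positive bound at 0, all other medians using fitted folds. Gene lists were written from general knowledge of liver biology and tested with limma camera at an inter-gene correlation of 0.01 and, as an alternative, with the correlation estimated from the residuals, each adjusted over the 31 lists. Some genes belong to several lists. Most estimated correlations lay above 0.01, among them erythroid (0.83), macrophage (0.739), coagulation (0.593) and P450 genes (0.432). Camera p-values at 0.01 may therefore be too small for such lists. Ranges of adjusted p given over the alternatives leave out the estimated correlation, whose adjusted p is given apart for each list. Counts adjusted over the list alone use the Benjamini-Hochberg method among the members of that list.

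Genes are named by a fixed rule. These are the 10 genes per direction with the largest fold among called genes well above background on all arrays and with groups that do not overlap, the 5 per direction with the largest bound, for each list the 3 members with the largest fitted fold in its more frequent direction, the 1 with the largest in the other and the first 2 uncalled members in list order, and a set of anchor genes. Some genes chosen by this rule are not reported here. Probe coordinates are those of the array files on mm9. Of 12734 genes with a RefSeq accession, 12425 were matched to a table of the reference assembly GRCm38.p6, which was used for names only, and 1299 of these had another current symbol. Of 3298 called genes with several tested probes, 124 had a probe called the other way.

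Alternatives were normexp background correction (offset 50), quantile normalization, both together, scaling to the median of probes detected on all arrays, scaling to 8 spike-in control probes, the deposited log2 values, other filters on dim probes, the mean of a gene's probes, eBayes with trend and robust, a 2-fold threshold, an adjusted p under 0.01, leaving out each array (the spread then comes from the other group alone), the replicate number as a block, and fry in place of camera. A crossed pairing of the replicates was added after the data were examined. A block for slide or scan was not possible with 1 slide and 1 scan time, and the filter on saturated probes had nothing to remove.

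The comparison was tested on simulated data with the spreads of these arrays, shuffled among genes and drawn independently for each gene. With 50 changed genes at each of the log2 folds 0.5, 1, 2 and 4 among 16421, the calls recovered 0, 0, 40 and 74% of them, and the median estimates were 0.49, 0.99, 2.02 and 3.98. Recovery at a log2 fold of 4 had first been set to reach 90% and did not. Of 59 genes called there, 2 were unchanged (3.39%). A second simulation had 10947 changed genes, near the number called on the arrays (10641). There 8864 were called, fewer than on the arrays, 159 of them unchanged (1.79%). Of those with a log2 fold of at least 2, 98.1% were recovered. On these simulated data the limma camera p-value was 8.39e-14 for a list of shifted genes and 0.793 for a random list. The shifted list was made of the genes with the largest simulated rise, and no genes were correlated. These values therefore do not test camera on lists of correlated genes, nor the share of false calls where genes vary together between replicates.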

Results

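Gene expression was measured on 4 one-colour Agilent mouse arrays, 2 hybridised with RNA of hepatoblasts from the liver at embryonic day 13 (E13 hepatoblasts) and 2 with RNA of hepatocytes from mice 8 weeks old (adult hepatocytes), all of the C57BL/6NCr strain. Hepatoblasts are the fetal liver progenitors that give rise to hepatocytes and bile duct cells. On the E13 arrays 23773 and 23049 of 41174 probes were well above background, against 20039 and 19299 on the adult arrays, and no spot was saturated. Arrays of one group correlated at Pearson r = 0.991 (E13) and 0.989 (adult) across the genes tested, and arrays of different groups at 0.727 to 0.742. No pair of arrays shared an identical signal at any of 17930 probes detected on all of them (0%), so all 4 were used as separate samples. The labels do not say whether the 2 samples of a group came from separate animals, so every p-value measures only the spread between these samples, which may be technical. Where 1 array is left out, its group is a single array and the spread comes from the other group alone, so a call gained that way shows only that the array left out carried the spread that had prevented it. The number of arrays limits the precision throughout, and values below are log2 signal relative to the array's 75th percentile, as mean ± SD with n = 2 per group. Log2 folds are given ± their standard error from limma.

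The comparison the series names is adult hepatocytes against E13 hepatoblasts. Fetal growth and oncofetal genes (Igf2, H19, Afp, Dlk1) were among the genes with the largest differences towards E13 hepatoblasts, and plasma and acute phase proteins, major urinary proteins and drug-metabolising enzymes among those towards adult hepatocytes. Afp, the fetal serum protein, was 9.36 ± 0.21 in E13 hepatoblasts and -1.66 ± 0.068 in adult hepatocytes, a log2 fold of -11.02 ± 0.17 (SE). Igf2, a fetal growth factor, was 8.95 ± 0.12 in E13 hepatoblasts and -5.69 ± 0.034 in adult hepatocytes, where it was not well above background, a difference of at least 5583-fold. Mup1, a major urinary protein, was -6.77 ± 0.23 in E13 hepatoblasts and 10.72 ± 0.059 in adult hepatocytes, higher in adult hepatocytes by at least 41745-fold since no E13 array detected it. Of 16421 genes tested, 5265 were called higher in adult hepatocytes and 5376 higher in E13 hepatoblasts by limma with Benjamini-Hochberg adjustment, of which 3698 and 3883 changed at least 2-fold. 1711 of the genes higher in E13 hepatoblasts were not well above background on either adult array, and 442 of those higher in adult hepatocytes on neither E13 array. In 85.7% of the genes both arrays of one group lay above both of the other, where chance gives 33.3%. The split between directions depended on the scaling. Scaling to spike-in RNA gave 2006 genes higher and 11272 lower in adult hepatocytes (15.1% of calls higher, against 49.5%), with the median of all genes at -1.24. This scaling moves the log2 fold of every gene alike, by -1.23. Normexp background correction gave 6647 higher and 4486 lower, with the median at 0.213. Folds below are therefore relative to the 75th percentile of each array.

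Among genes well above background on all 4 arrays, the largest differences towards adult hepatocytes were in Serpina3m (11349.8-fold), Lrg1 (5664-fold), Ces3b (2739-fold), Igf1 (1857-fold), Saa1 (1568-fold), G6pc (1452-fold), Fbp1 (1344-fold), Saa3 (1205-fold), Aldh1a1 (1200.2-fold) and Inmt (1134-fold). They include secreted inflammation-related proteins, Igf1 (the growth factor of postnatal life) and the gluconeogenic enzymes G6pc and Fbp1. Towards E13 hepatoblasts, the largest were in H19 (3958-fold), Afp (2074-fold), Meg3 (902-fold), Scd2 (695-fold), Ngfrap1 (now Bex3; 525-fold), Grb10 (412-fold), Mogat2 (343-fold), Cdkn1c (306-fold), Plagl1 (232-fold) and Mki67 (212-fold). H19, Meg3, Grb10, Cdkn1c and Plagl1 are imprinted genes, and Mki67 is a marker of dividing cells. Among genes that 1 group did not show well above background, the largest bounds towards adult hepatocytes were in Saa2 (at least 42900.2-fold), Mup1 (at least 41745-fold), Serpina3k (at least 31924-fold), Mup5 (at least 28266-fold) and Mup3 (at least 26564-fold), and towards E13 hepatoblasts in Igf2 (at least 5583-fold), Phgdh (at least 2518-fold), the first enzyme of serine synthesis, Bex2 (at least 1496-fold), Bex1 (at least 1177-fold) and Acss1 (at least 467-fold). Probes of multigene families such as Mup, Saa and Serpina3 can bind transcripts of close relatives, so a value there may cover several members. In mm9 coordinates, the Afp probe lay on chromosome 5 from 90937781 to 90937840, the H19 probe on chromosome 7 from 149761769 to 149761828, the Cyp2e1 probe on chromosome 7 from 147959585 to 147959644 and the Serpina3m probe on chromosome 12 from 105632342 to 105632400. Leaving out either E13 array moved the log2 value of Ces3b (10.06 to 12.78), Fbp1 (9.36 to 11.42) and Plagl1 (-8.48 to -7.25). The log2 value of Grb10 (-9.50 to -7.87) and Mogat2 (-9.04 to -7.81) moved on leaving out either adult array.

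**Figure D1:**
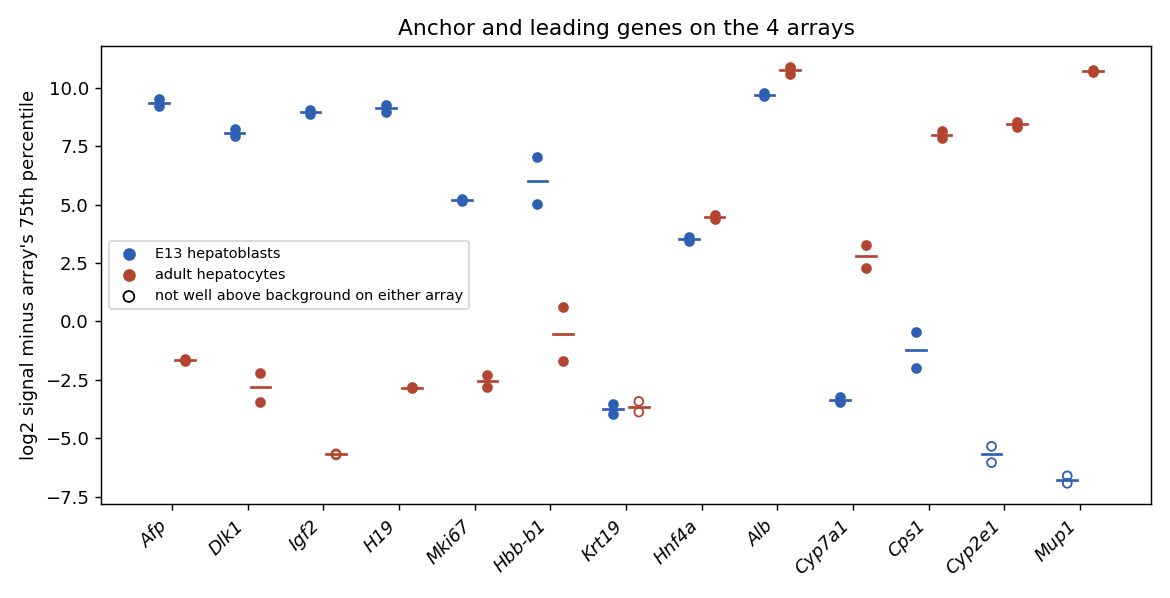
Signal of 13 genes (log2 relative to the array's 75th percentile, vertical axis) on the 2 E13 and 2 adult arrays, with the group mean as a bar and open circles where neither array of the group was well above background. Afp, Dlk1, Igf2, H19 and Mki67 were higher in E13 hepatoblasts and Cyp7a1, Cps1, Cyp2e1 and Mup1 in adult hepatocytes, while Alb differed by 1.05 and Hnf4a by 0.94, both of which fell below 0 under spike-in scaling.

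Genes of the fetal liver programme were higher in E13 hepatoblasts. Of 15 hepatoblast and oncofetal genes measured, 0 were called higher in adult hepatocytes, 14 higher in E13 hepatoblasts and 1 neither (the same adjusted over the list alone). Hepatoblast and oncofetal genes had a median log2 fold of -7.32 (-6.20 with bounded genes at their bounds), with camera adjusted p = 5.56e-08, and adjusted p = 0.302 with an estimated correlation. This median was -4.50 with normexp correction and -2.67 with probes detected on all arrays. Igf2, H19 and Afp led. The receptor Met was not called, at a log2 fold of 0.38 ± 0.18 that turned to -0.85 under spike-in scaling, although 1 of its 3 probes was called higher in adult hepatocytes. Of 17 imprinted genes, 1 was called higher in adult hepatocytes, 14 higher in E13 hepatoblasts and 2 neither (the same adjusted over the list alone). Imprinted genes had a median log2 fold of -6.82 (-6.20 with bounded genes at their bounds), with camera adjusted p = 1.01e-05, and adjusted p = 0.302 with an estimated correlation. It was -4.54 with normexp correction and -3.41 with probes detected on all arrays. Besides Igf2 and H19, Dlk1, a Notch-family surface protein of hepatoblasts, was 8.08 ± 0.22 in E13 hepatoblasts and -2.83 ± 0.88 in adult hepatocytes, a 1923-fold difference, with 1 of the 2 adult arrays well above background. Slc38a4, an amino acid transporter, was the imprinted gene called the other way (4.36-fold), and Gnas (-0.16 ± 0.14) and Dcn (-0.49 ± 0.60) were not called, although 1 of 3 Gnas probes was called higher in E13 hepatoblasts. Without E13 replicate 2, Dcn was called at -1.34. On leaving out either adult array the log2 value changed for Dlk1 (-11.53 to -10.29).

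Liver transcription factors were called in both directions. Of 25 measured, 12 were called higher in adult hepatocytes, 2 higher in E13 hepatoblasts and 11 neither (the same adjusted over the list alone). Liver transcription factors had a median log2 fold of 0.55, with camera adjusted p = 0.0097, and adjusted p = 0.302 with an estimated correlation, and the median turned to -0.68 under spike-in scaling. The list lost its camera call with normexp correction (limma adjusted p = 0.086) and no filter on dim probes (0.266; 0.00266 to 0.266 over the alternatives). Nuclear receptors led: Nr0b2 (72.2-fold), Nr1i3 (23.7-fold) and Nr1h4 (17.1-fold), the bile acid receptor, were higher in adult hepatocytes. Gata6 was higher in E13 hepatoblasts (3.79-fold), although 1 of its 3 probes was called the other way. Hnf4a, a central hepatocyte regulator, was 3.52 ± 0.12 in E13 hepatoblasts and 4.46 ± 0.11 in adult hepatocytes, a log2 fold of 0.94 ± 0.16 (limma adjusted p = 0.00652) that became -0.29 under spike-in scaling.

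Plasma protein genes were higher in adult hepatocytes. Of 26 secreted plasma proteins, 24 were called higher in adult hepatocytes, 2 higher in E13 hepatoblasts and 0 neither (the same adjusted over the list alone). Secreted plasma proteins had a median log2 fold of 1.84, with camera adjusted p = 2.3e-06, and adjusted p = 0.302 with an estimated correlation. This median was 0.93 with quantile normalization, 0.88 with normexp and quantile together and 0.61 with spike-in scaling. Azgp1 (790.3-fold), Apoc3 (442-fold) and haptoglobin, Hp (382-fold), rose most. Serpina6, the carrier of glucocorticoids, was higher in E13 hepatoblasts (8.12-fold). Alb, serum albumin, was already high before birth, 9.70 ± 0.086 in E13 hepatoblasts and 10.75 ± 0.21 in adult hepatocytes. Its log2 fold of 1.05 ± 0.17 (limma adjusted p = 0.00648) turned to -0.24 under quantile normalization and -0.18 under spike-in scaling. Of 29 coagulation and complement factors, 28 were called higher in adult hepatocytes, 0 higher in E13 hepatoblasts and 1 neither (the same adjusted over the list alone). Coagulation and complement factors had a median log2 fold of 2.03, with camera adjusted p = 3e-09, and adjusted p = 0.409 with an estimated correlation, and the median was 0.80 with spike-in scaling. C6 (542-fold), C9 (508-fold) and Mbl2 (209.9-fold) led, with C6 and C9 well above background on 1 of the 2 E13 arrays. C6 also belongs to the list of male-biased liver genes below. Serpind1 was not called, at 0.41 ± 0.21 (-0.83 under spike-in scaling, and 0.63 and called without adult replicate 1). Of 24 acute phase genes, 19 were called higher in adult hepatocytes, 1 higher in E13 hepatoblasts and 4 neither (the same adjusted over the list alone). Acute phase genes had a median log2 fold of 5.96, with camera adjusted p = 2.15e-07, and adjusted p = 0.302 with an estimated correlation. The acute phase median was 4.25 with probes detected on all arrays, 6.60 without E13 replicate 1 and 5.21 without E13 replicate 2. Saa2 (at least 42900.2-fold), Orm2 (at least 7132-fold) and Orm1 (at least 5948-fold) were among the genes called higher in adult hepatocytes. In adult hepatocytes Saa1 (10.89 ± 0.15) and Saa2 (10.76 ± 0.11) were about as high as Alb. Whether the acute phase difference came from development or from an acute phase response in the adult samples was not tested. Mt1 was higher in E13 hepatoblasts (2.01-fold), a call lost without E13 replicate 1 (limma adjusted p = 0.126) or E13 replicate 2 (0.141; 0.000686 to 0.141 over the alternatives). Socs3 (-0.46 ± 0.46) and Stat3 (0.68 ± 0.32) were not called with all 4 arrays. Without adult replicate 1 Socs3 was called at -1.07, and without adult replicate 2 Stat3 was called at 1.10. Leaving out either E13 array moved the log2 value of Azgp1 (8.79 to 10.46) and Hp (7.80 to 9.35). The log2 value of Serpina6 (-3.61 to -2.43) moved on leaving out either adult array.

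Enzymes of drug and bile acid metabolism were higher in adult hepatocytes. All 29 cytochrome P450s of drug metabolism were called higher in adult hepatocytes, over all genes and adjusted over the list alone. Cytochrome P450s of drug metabolism had a median log2 fold of 7.09 (6.97 with bounded genes at their bounds), with camera adjusted p = 1.22e-11, and adjusted p = 0.302 with an estimated correlation. Cyp2e1 (at least 8578-fold) and Cyp3a25 (at least 2767-fold) were not well above background on either E13 array, and Cyp2f2 (13477-fold) on 1 of 2. Of 29 conjugation enzymes, 27 were called higher in adult hepatocytes, 0 higher in E13 hepatoblasts and 2 neither (the same adjusted over the list alone). Conjugation enzymes had a median log2 fold of 4.80, with camera adjusted p = 6.58e-11, and adjusted p = 0.302 with an estimated correlation. Nnmt (at least 4311-fold), Ugt2a3 (at least 1402-fold) and Inmt (1134-fold) were among the genes called. Ugt2b34 (0.19 ± 0.17) and Gstt1 (0.31 ± 0.15) were not called and lay at -1.04 and -0.93, past the threshold, under spike-in scaling. All 25 genes of bile acid synthesis and transport were called higher in adult hepatocytes, likewise adjusted over the list alone. Bile acid synthesis and transport had a median log2 fold of 5.73 (5.22 with bounded genes at their bounds), with camera adjusted p = 3.59e-11, and adjusted p = 0.302 with an estimated correlation, and the median was 3.54 with normexp and quantile together. Cyp7b1 (765-fold) and the uptake transporters Slco1b2 (483-fold) and Slco1a1 (at least 157-fold) were among them. Cyp7b1 and Slco1a1 also belong to the list of male-biased liver genes below, and the labels give no sex for the animals. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was -3.35 ± 0.17 in E13 hepatoblasts and 2.78 ± 0.69 in adult hepatocytes (70.2-fold, limma adjusted p = 0.000342). P450 probes of one subfamily can cross-hybridise. On leaving out either E13 array the log2 value changed for Cyp2f2 (12.78 to 14.66) and Slco1b2 (8.29 to 9.54).

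Amino acid catabolism followed the same direction. Of 34 genes of the urea cycle and amino acid catabolism, 33 were called higher in adult hepatocytes, 0 higher in E13 hepatoblasts and 1 neither (the same adjusted over the list alone). Urea cycle and amino acid catabolism had a median log2 fold of 3.35, with camera adjusted p = 4.41e-12, and adjusted p = 0.302 with an estimated correlation, and the median was 2.11 with spike-in scaling. Sds (2058-fold, well above background on 1 E13 array), Tdo2 (at least 1220.2-fold) and Cps1 were among the genes called. Cps1, the first enzyme of the urea cycle, was -1.23 ± 1.10 in E13 hepatoblasts and 7.99 ± 0.20 in adult hepatocytes, a 597-fold difference (limma adjusted p = 0.000343). The glycine-cleavage enzyme Gldc was at 0.072 ± 0.23 (-1.16 under spike-in scaling). Of 18 genes of gluconeogenesis and liver-type sugar metabolism, 11 were called higher in adult hepatocytes, 4 higher in E13 hepatoblasts and 3 neither (12 and 4 adjusted over the list alone). The list members Pck1 and Tkfc had no probe under these names and were not tested. Gluconeogenesis and liver-type sugar metabolism had a median log2 fold of 1.34, with camera adjusted p = 0.0229, and adjusted p = 0.442 with an estimated correlation. The sugar list had a median of 0.76 with quantile normalization, 0.73 with normexp and quantile together and 0.11 with spike-in scaling. G6pc (1452-fold) and Fbp1 (1344-fold) rose, and Galk1 was higher in E13 hepatoblasts (6.43-fold). Gys2 (-0.69 ± 0.28) and Slc2a2 (1.06 ± 0.37) were not called with all arrays, although 1 of 2 Slc2a2 probes was called higher in adult hepatocytes. Without adult replicate 2 Gys2 was called at -1.06, and without adult replicate 1 Slc2a2 was called at 1.58. It lost its camera call with normexp correction (limma adjusted p = 0.086), no filter on dim probes (0.309) and probes detected on all arrays (0.124; 0.000356 to 0.309 over the alternatives). Of 18 glycolysis genes with non-liver isoforms, 0 were called higher in adult hepatocytes, 11 higher in E13 hepatoblasts and 7 neither (the same adjusted over the list alone). Glycolysis genes with non-liver isoforms had a median log2 fold of -0.92, with camera adjusted p = 0.00134, and adjusted p = 0.302 with an estimated correlation, and the median was -2.15 with spike-in scaling and -0.60 with probes detected on all arrays. Ldhb (82.6-fold), Hk2 (at least 15.2-fold) and Slc16a3 (68.3-fold) were lower in adult hepatocytes. Pfkp (0.11 ± 0.36) and Pfkm (0.41 ± 0.14) were not called and turned to -1.12 and -0.82 under spike-in scaling. Of 2 Pfkp probes 1 was called higher in E13 hepatoblasts. Leaving out either E13 array moved the log2 value of Cps1 (8.44 to 10).

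Lipid and respiratory genes divided. Of 29 genes of fatty acid oxidation and ketogenesis, 21 were called higher in adult hepatocytes, 2 higher in E13 hepatoblasts and 6 neither (22 and 2 adjusted over the list alone). Fatty acid oxidation and ketogenesis had a median log2 fold of 1.45, with camera adjusted p = 3.48e-05, and adjusted p = 0.458 with an estimated correlation, and the median was 0.21 with spike-in scaling. The fatty acid hydroxylases Cyp4a14 (at least 1227-fold) and Cyp4a10 (126-fold) were among the genes called. Acot1 was higher in E13 hepatoblasts (5.36-fold), and Acadl (-0.47 ± 0.23) and Hadha (-0.16 ± 0.16) were not called. Cholesterol synthesis went the other way. Of 24 genes, 3 were called higher in adult hepatocytes, 17 higher in E13 hepatoblasts and 4 neither (3 and 18 adjusted over the list alone). Cholesterol synthesis had a median log2 fold of -2.51, with camera adjusted p = 0.000188, and adjusted p = 0.302 with an estimated correlation. Sqle (log2 fold -6.75 ± 0.19) and Mvd (24.2-fold), enzymes of the pathway, fell. Ebp rose (2.66-fold) but missed the threshold under spike-in scaling (0.18), and Tm7sf2 (-0.055 ± 0.15) was not called. Of 25 genes of the mitochondrial respiratory chain, 16 were called higher in adult hepatocytes, 0 higher in E13 hepatoblasts and 9 neither (the same adjusted over the list alone). Mitochondrial respiratory chain had a median log2 fold of 0.56, with camera adjusted p = 0.000484, and adjusted p = 0.449 with an estimated correlation. The camera call was lost under normexp correction (limma adjusted p = 0.0547), quantile normalization (0.712), both together (0.758), spike-in scaling (0.672) and no filter on dim probes (0.058; 0.000266 to 0.758 over the alternatives). The median turned to -0.023 with quantile normalization, -0.022 with normexp and quantile together and -0.68 with spike-in scaling. Cox6c (3.82-fold), Sdhb (3-fold) and Sdha (2.74-fold) led, and Ndufs1 (0.36 ± 0.15) and Ndufv2 (0.12 ± 0.15) were not called. Under spike-in scaling Sdhb and Sdha missed the threshold and Ndufs1 and Ndufv2 lay at -0.87 and -1.11. The log2 value of Cyp4a14 (bound 9.09 to 11.43) moved on leaving out either adult array.

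Cell division genes were lower in adult hepatocytes. Of 28 mitosis genes, 0 were called higher in adult hepatocytes, 26 higher in E13 hepatoblasts and 2 neither (the same adjusted over the list alone). Mitosis genes had a median log2 fold of -6.24 (-5.52 with bounded genes at their bounds), with camera adjusted p = 1.22e-11, and adjusted p = 0.302 with an estimated correlation, and the median was -3.91 with normexp correction. Top2a (at least 67.2-fold) and Cdk1 (at least 80.8-fold) were not well above background on either adult array, and Mki67 was 5.18 ± 0.061 in E13 hepatoblasts and -2.54 ± 0.38 in adult hepatocytes (212-fold, limma adjusted p = 8.39e-05). Bub1 was at -0.50 ± 0.21, with another of its probes called lower, and was itself called without adult replicate 1 (-0.73), and Anln at -2.02 ± 1.85. Anln was called lower without adult replicate 1 (-4.79) and higher without adult replicate 2 (0.74), its adult values being 0.045 and -5.49. Of 2 Anln probes 1 was called higher in E13 hepatoblasts. Of 31 DNA replication genes, 1 was called higher in adult hepatocytes, 29 higher in E13 hepatoblasts and 1 neither (the same adjusted over the list alone). DNA replication genes had a median log2 fold of -3.24 (-3.14 with bounded genes at their bounds), with camera adjusted p = 1.1e-10, and adjusted p = 0.302 with an estimated correlation. Cdc6 (at least 17.9-fold), Rrm2 (41.7-fold) and Mcm5 (39.4-fold) fell, Rrm2 with 1 adult array well above background. Mcm10 was called higher (4.93-fold, from 1 probe). Of 21 DNA methylation and chromatin regulators, 2 were called higher in adult hepatocytes, 14 higher in E13 hepatoblasts and 5 neither (3 and 15 adjusted over the list alone). DNA methylation and chromatin regulators had a median log2 fold of -1.18 (-1.10 with bounded genes at their bounds), with camera adjusted p = 0.00112, and adjusted p = 0.302 with an estimated correlation, and the median was -2.41 with spike-in scaling. Uhrf1 and Hells, which act with maintenance methylation, were lower in adult hepatocytes by at least 160.2-fold and at least 12.3-fold, as was Hmgb2 (36-fold). The Polycomb gene Cbx7 was higher (at least 14.1-fold), and Dnmt3b (-1.10 ± 0.47) and Tet2 (-0.40 ± 0.20) were not called. Both passed without adult replicate 1 (-1.78 and -0.60).

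Hepatocytes differ along the lobule, and genes of both zones were compared. Of 16 periportal genes, 14 were called higher in adult hepatocytes, 1 higher in E13 hepatoblasts and 1 neither (14 and 2 adjusted over the list alone). Pck1, also on this list, had no probe under this name. Periportal zone genes had a median log2 fold of 6.27, with camera adjusted p = 2.86e-06, and adjusted p = 0.377 with an estimated correlation. Cyp2f2, Agxt2l1 (now Etnppl; at least 1202-fold) and Sds were among the genes called. Cdh1 was higher in E13 hepatoblasts (2.48-fold), and Aldh1b1 was at -1.02 ± 0.36, passing without adult replicate 2 (-1.51). Of 15 pericentral genes, 9 were called higher in adult hepatocytes, 3 higher in E13 hepatoblasts and 3 neither (the same adjusted over the list alone). Pericentral zone genes had a median log2 fold of 0.66, with camera adjusted p = 0.0283, and adjusted p = 0.442 with an estimated correlation, and the median turned to -0.58 under spike-in scaling. The pericentral camera call was lost with normexp correction (limma adjusted p = 0.0907), quantile normalization (0.114), normexp and quantile together (0.0791), no filter on dim probes (0.309), probes detected on all arrays (0.416) and leaving out adult replicate 2 (0.079; 0.00156 to 0.416 over the alternatives). Cyp2e1, Aldh1a1 and Cyp1a2 (at least 423-fold) rose and the ammonium transporter Rhbg fell (11.1-fold), while glutamine synthetase, Glul, was at 0.45 ± 0.25 and Lect2 at -0.14 ± 0.21. Without adult replicate 1 Glul was called higher (0.74), and spike-in scaling turned it to -0.79. The labels give no sex for the animals. All 14 male-biased liver genes measured were called higher in adult hepatocytes, also adjusted over the list alone. Male-biased liver genes had a median log2 fold of 8.23 (7.33 with bounded genes at their bounds), with camera adjusted p = 2.15e-07, and adjusted p = 0.302 with an estimated correlation. They include Elovl3 (at least 692-fold), Cyp4a12b (at least 436-fold) and Cyp4a12a (1003-fold, well above background on 1 E13 array). Of 15 female-biased genes, 9 were called higher in adult hepatocytes, 5 higher in E13 hepatoblasts and 1 neither (10 and 5 adjusted over the list alone). Female-biased liver genes had a median log2 fold of 3.79 (2.69 with bounded genes at their bounds), with camera adjusted p = 0.246, and adjusted p = 0.645 with an estimated correlation. The female-biased median was 1.69 with normexp correction, 1.18 with normexp and quantile together and 2.36 with no filter on dim probes. The list passed by camera with spike-in scaling (limma adjusted p = 0.00139) and probes detected on all arrays (0.0228). Between the adult arrays (replicate 1 minus replicate 2) the female-biased genes differed by a median of -0.92 and the male-biased genes by 0.56. The fry test gave the opposite direction, towards E13 hepatoblasts (limma adjusted p = 0.0455; 0.00139 to 0.686 over the alternatives). Cyp4a14 (at least 1227-fold), Cyp2a4 (867-fold) and Cyp2b9 (321-fold, well above background on 1 E13 array) were higher in adult hepatocytes and Prom1 in E13 hepatoblasts (at least 18.8-fold). Cyp17a1 was at 0.68 ± 0.25, called without adult replicate 2 (0.93). On leaving out either adult array the log2 value changed for Elovl3 (bound 8.61 to 10.25) and Cyp4a12a (9.38 to 10.56). Leaving out either E13 or either adult array moved the log2 value of Cyp2a4 (8.76 to 10.76) and Cyp2b9 (7.48 to 9.18).

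**Figure D2:**
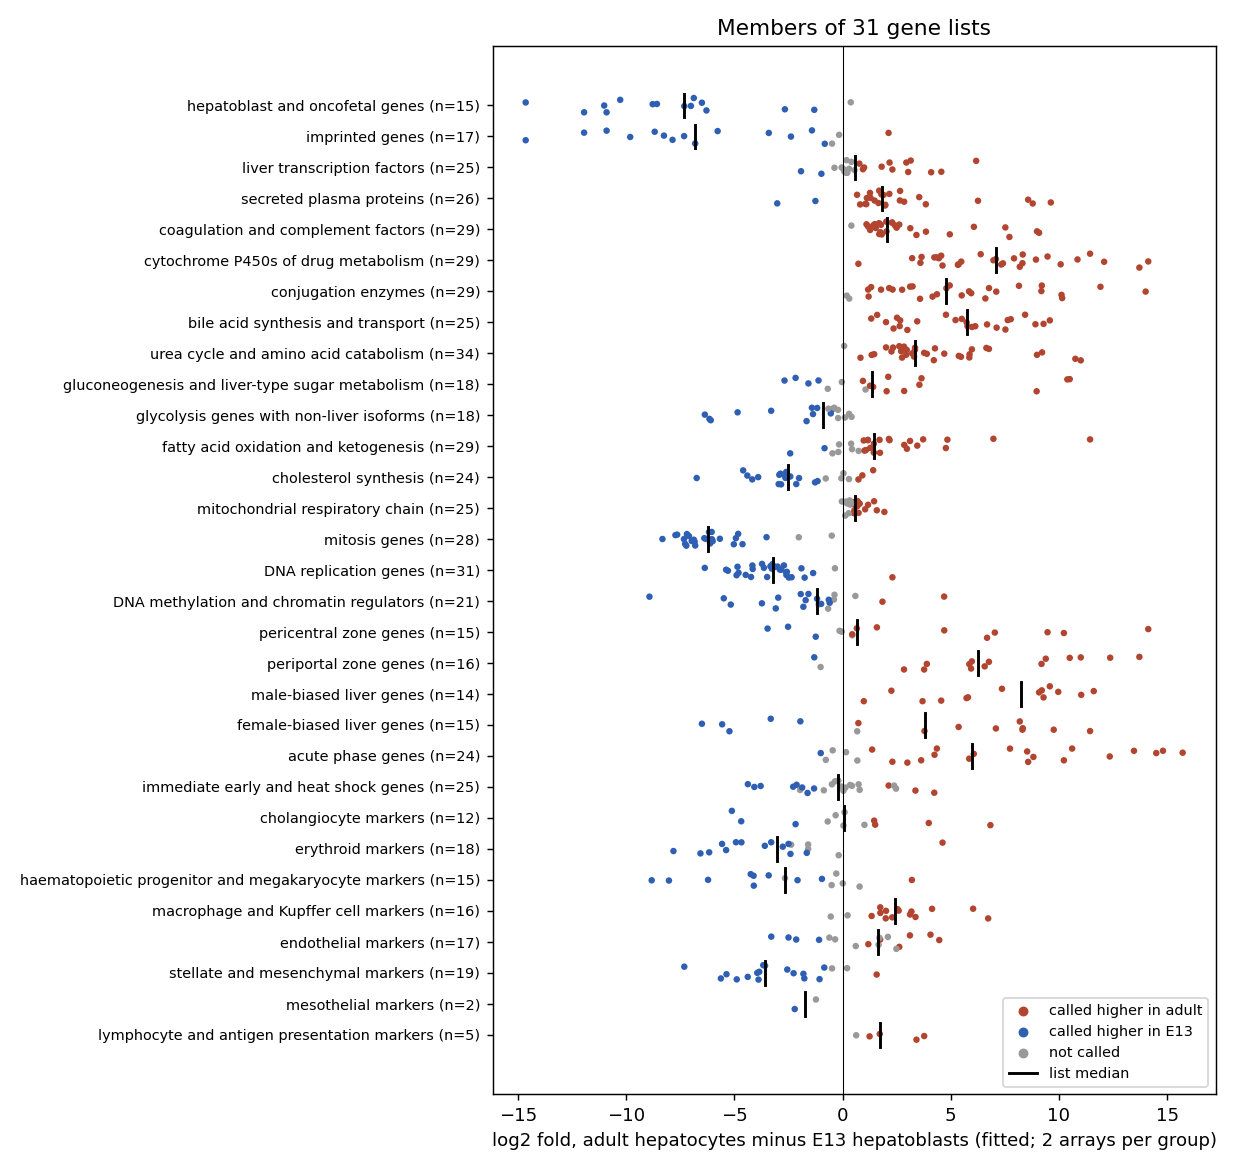
Fitted log2 fold (adult minus E13, horizontal axis) of each measured member of 31 gene lists, coloured by its call, with the list median as a black bar; genes not well above background in 1 group are drawn at their fitted value, not at their bound. P450, bile acid and urea cycle genes lay to the right and hepatoblast, imprinted and mitosis genes to the left, while the medians of liver transcription factors, respiratory chain, pericentral and cholangiocyte genes fell below 0 under spike-in scaling, and that of mesothelial genes rose above 0 under normexp correction.

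Blood cell markers differed between the groups and between the E13 arrays. Of 18 erythroid markers, 1 was called higher in adult hepatocytes, 13 higher in E13 hepatoblasts and 4 neither (1 and 14 adjusted over the list alone). Erythroid markers had a median log2 fold of -3.03 (-2.32 with bounded genes at their bounds), with camera adjusted p = 0.00193, and adjusted p = 0.534 with an estimated correlation. The erythroid median was -1.15 with normexp correction and -1.54 with normexp and quantile together. It was -2.15 without E13 replicate 1 and -3.93 without E13 replicate 2. The erythroid list missed the threshold with spike-in scaling (limma adjusted p = 0.164), probes detected on all arrays (0.0802) and fry (0.0698; 8.98e-08 to 0.164 over the alternatives). Ahsp (at least 53.1-fold), Hbb-b1 (95-fold) and Hba-a1 (71.9-fold) were higher in E13 hepatoblasts. Hbb-b1, whose probe's accession is now named Hbb-bt, was 6.03 ± 1.44 in E13 hepatoblasts and -0.55 ± 1.63 in adult hepatocytes, with 7.04 and 5.01 on the 2 E13 arrays. Alas2, the erythroid form of the first haem enzyme, went the other way (24.6-fold). The embryonic globins Hbb-y (fitted -1.59 ± 0.61) and Hbb-bh1 (fitted -2.38 ± 0.83) were not called and not well above background on either adult array. Bounds computed from the group means were 2.54-fold and 1.82-fold, but neither gene was called, so these are not minimum differences. Both genes passed with the replicate block and lay at -2.48 and -3.39 without E13 replicate 2. Of 2 Hbb-bh1 probes 1 was called higher in E13 hepatoblasts. Of 15 haematopoietic progenitor and megakaryocyte markers, 1 was called higher in adult hepatocytes, 9 higher in E13 hepatoblasts and 5 neither (1 and 10 adjusted over the list alone). Haematopoietic progenitor and megakaryocyte markers had a median log2 fold of -2.66 (-1.76 with bounded genes at their bounds), with camera adjusted p = 0.0117, and adjusted p = 0.534 with an estimated correlation. The progenitor and megakaryocyte median was -0.66 with normexp correction, -1.11 with normexp and quantile together, -0.95 with no filter on dim probes, 0.0078 with probes detected on all arrays and -1.70 without E13 replicate 1, against -3.56 without E13 replicate 2. This camera call was lost with spike-in scaling (limma adjusted p = 0.174) and probes detected on all arrays (0.727; 0.000159 to 0.727 over the alternatives). The platelet genes Pf4 (at least 233-fold), Ppbp (at least 59.3-fold) and Gp9 (at least 22.4-fold) were higher in E13 hepatoblasts and Prtn3 in adult hepatocytes (9.2-fold). Kit, not well above background on either adult array, had a fitted log2 fold of -0.29 ± 0.37 (0.53 and called under normexp correction). Cd34 was at -0.51 ± 0.78 (-1.62 without E13 replicate 2). All 18 erythroid markers were higher on E13 replicate 1 than on E13 replicate 2, with a median difference of 1.87. The log2 value of Ahsp (bound 4.68 to 6.78) and Alas2 (3.76 to 5.48) moved on leaving out either E13 array. On leaving out either E13 or either adult array the log2 value changed for Hbb-b1 (-7.72 to -5.42) and Hba-a1 (-7.43 to -4.91).

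Macrophage markers were higher in adult hepatocytes. Of 16 macrophage and Kupffer cell markers, 14 were called higher in adult hepatocytes, 0 higher in E13 hepatoblasts and 2 neither (the same adjusted over the list alone). Macrophage and Kupffer cell markers had a median log2 fold of 2.42 (2.15 with bounded genes at their bounds), with camera adjusted p = 0.000478, and adjusted p = 0.475 with an estimated correlation. The macrophage median was 1.35 with normexp correction, 0.95 with normexp and quantile together and 1.18 with spike-in scaling. It was 2.99 without E13 replicate 1 and 1.63 without E13 replicate 2. Mpeg1 (106-fold) and Clec4f (at least 18.8-fold), a Kupffer cell lectin, were called higher. So was Cd5l (17.6-fold; limma adjusted p = 0.0584 and 0.0518 without adult replicate 1 or 2; 8.45e-05 to 0.0584 over the alternatives). Cd68 (0.23 ± 0.31) and Marco (-0.55 ± 0.41) were not called. Ptprc, the pan-leukocyte surface protein, was not tested, since none of its 4 probes was well above background on both arrays of a group, and 1 probe was so on 1 adult array. Of 5 lymphocyte and antigen presentation markers, 4 were called higher in adult hepatocytes, 0 higher in E13 hepatoblasts and 1 neither (the same adjusted over the list alone). Lymphocyte and antigen presentation markers had a median log2 fold of 1.72, with camera adjusted p = 0.0228, and adjusted p = 0.302 with an estimated correlation, and the median was 1.14 with normexp correction, 0.87 with normexp and quantile together and 0.48 with spike-in scaling. Another 12 of the 17 members were not tested, and the camera call was lost without the filter on dim probes (limma adjusted p = 0.142) and with probes detected on all arrays (0.205; 0.00309 to 0.205 over the alternatives). H2-Ab1 (at least 10-fold) and Cd74 (log2 fold 3.42 ± 0.20, well above background on 1 E13 array) were higher in adult hepatocytes, as was Ccl5 (3.29-fold), which missed the threshold under spike-in scaling (0.49). Of 17 endothelial markers, 6 were called higher in adult hepatocytes, 4 higher in E13 hepatoblasts and 7 neither (the same adjusted over the list alone). Endothelial markers had a median log2 fold of 1.66, with camera adjusted p = 0.498, and adjusted p = 0.835 with an estimated correlation. The endothelial median was 1.00 with normexp correction, 0.54 with normexp and quantile together, 0.43 with spike-in scaling, 0.61 with probes detected on all arrays and 0.61 without E13 replicate 2, against 2.24 without E13 replicate 1. This list passed by camera with spike-in scaling (limma adjusted p = 0.0252) and leaving out E13 replicate 1 (0.021), and its adjusted p from limma was 0.021 to 0.684 over the alternatives. Clec4g (22.1-fold), Fcgr2b (at least 10.1-fold) and Robo4 (8.65-fold, well above background on 1 E13 array) were higher in adult hepatocytes and Egfl7 in E13 hepatoblasts (9.84-fold). Cdh5 (2.09 ± 1.00, well above background on 1 E13 array) and Tek (fitted -0.35 ± 0.17, well above background on neither adult array) were not called. The Robo4 call was lost under spike-in scaling and without adult replicate 1 or 2 (limma adjusted p = 0.11 and 0.135; 0.000823 to 0.135 over the alternatives), and Cdh5 was called at 3.58 without E13 replicate 1. Leaving out either E13 array moved the log2 value of Cd5l (2.90 to 5.37), Clec4g (3.74 to 5.19) and Robo4 (1.75 to 4.47).

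Stromal and biliary markers were also read. Of 19 stellate and mesenchymal markers, 1 was called higher in adult hepatocytes, 16 higher in E13 hepatoblasts and 2 neither (the same adjusted over the list alone). Stellate and mesenchymal markers had a median log2 fold of -3.58 (-2.56 with bounded genes at their bounds), with camera adjusted p = 0.000299, and adjusted p = 0.458 with an estimated correlation, and the median was -1.91 with normexp correction and -2.11 with normexp and quantile together. Reln (159.6-fold), Col1a1 (at least 39.6-fold) and Col5a1 (at least 17.1-fold) were higher in E13 hepatoblasts, although another Col5a1 probe was detected in adult hepatocytes. Tagln was at 0.21 ± 0.23 (-1.02 under spike-in scaling). Ecm1 was higher in adult hepatocytes (2.98-fold), a call lost without adult replicate 1 or 2 (and under spike-in scaling; limma adjusted p = 0.0997 and 0.096; 0.00429 to 0.502 over the alternatives). Of 12 cholangiocyte markers tested (7 were not), 4 were called higher in adult hepatocytes, 3 higher in E13 hepatoblasts and 5 neither (the same adjusted over the list alone). Cholangiocyte markers had a median log2 fold of 0.065 (0.019 with bounded genes at their bounds), with camera adjusted p = 0.91, and adjusted p = 0.958 with an estimated correlation. The median turned to -1.17 under spike-in scaling and was 0.0053 to 0.69 over the other alternatives. Spp1 (at least 52.4-fold), Aqp1 (15.8-fold) and St14 (at least 2.49-fold) were higher in adult hepatocytes and Ggt1 in E13 hepatoblasts (at least 9.14-fold). The St14 call was lost under spike-in scaling (0.27). The Aqp1 call was lost without adult replicate 1 or 2 (limma adjusted p = 0.0533 and 0.0781; 0.000281 to 0.0781 over the alternatives). Krt19, a keratin of bile ducts, was -3.75 ± 0.32 in E13 hepatoblasts and -3.65 ± 0.32 in adult hepatocytes and not well above background on either adult array, and Krt7 was at -0.69 ± 0.41. Of 2 mesothelial markers tested (7 were not), 0 were called higher in adult hepatocytes, 1 higher in E13 hepatoblasts and 1 neither (the same adjusted over the list alone). Mesothelial markers had a median log2 fold of -1.72 (0.00 with bounded genes at their bounds), with camera adjusted p = 0.246, and adjusted p = 0.475 with an estimated correlation, and the median was 0.18 with normexp correction, -0.46 with normexp and quantile together, -2.96 with spike-in scaling and -0.34 with no filter on dim probes. Wt1, called higher in E13 hepatoblasts (limma adjusted p = 0.0036), lay too near background for a bound on its fold and turned to 0.058 under normexp correction. Aldh1a2, not well above background on either adult array, was not called (fitted log2 fold -1.23 ± 0.53, and -1.97 without adult replicate 1). Immediate early and heat shock genes, which respond to cell isolation, were called in both directions. Of 25, 3 were called higher in adult hepatocytes, 8 higher in E13 hepatoblasts and 14 neither (3 and 7 adjusted over the list alone). Immediate early and heat shock genes had a median log2 fold of -0.20 (-0.071 with bounded genes at their bounds), with camera adjusted p = 0.45, and adjusted p = 0.835 with an estimated correlation. The adult arrays differed on this list by a median of 0.99 (replicate 1 minus replicate 2), and the median fold was -0.076 with normexp correction, -1.43 with spike-in scaling, -0.017 with probes detected on all arrays, -0.73 without adult replicate 1 and 0.35 without adult replicate 2. The list passed by camera with no filter on dim probes (limma adjusted p = 0.00964), and its adjusted p from limma was 0.00964 to 0.841 over the alternatives. Egr2 (at least 5.87-fold), Klf6 (16.9-fold) and Myc (13.8-fold) were higher in E13 hepatoblasts and the heat shock gene Hspb1 in adult hepatocytes (18.9-fold). Fos (0.037 ± 0.57) and Jun (-0.20 ± 0.47) were not called. The log2 value of Col1a1 (bound 4.64 to 5.98), Ecm1 (0.97 to 2.18) and Aqp1 (2.70 to 5.26) moved on leaving out either E13 array.

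**Figure D3:**
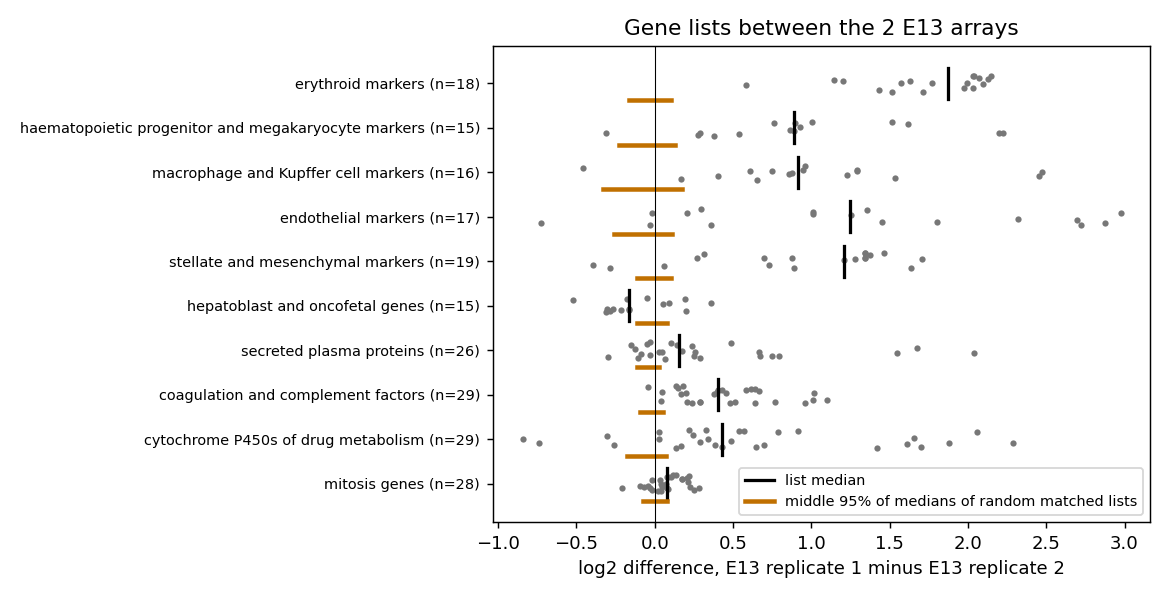
Log2 difference between the 2 E13 arrays (replicate 1 minus replicate 2, horizontal axis) of each member of 10 gene lists, with the list median in black and the middle 95% of medians of random lists of the same size and E13 level in orange. Erythroid (1.87), endothelial (1.25), stellate (1.21), macrophage (0.91) and progenitor and megakaryocyte markers (0.89) lay to the right, and hepatoblast and oncofetal genes at -0.16.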

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

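Apart from the estimated correlation, 21 of 31 lists and 125 of 188 named genes stayed called one way, or uncalled either way, wherever tested. Of these lists, 19 kept the sign of their median. The cause of the changes below was not tested. Adjusted p-values of lists are from limma camera over all lists, and values of genes are log2 folds, adult minus E13. The directions depended most on the scaling. Spike-in scaling gave 2006 genes higher and 11272 lower in adult hepatocytes, with 588 of the main calls in the other direction and 7382 in the same. Without a filter on dim probes 20059 genes were called, 14588 of them higher and 5471 lower in adult hepatocytes, and with probes detected on all arrays 8513 were called, 4819 and 3694. Normexp correction gave 6647 and 4486, quantile normalization 4990 and 5976, both together 4904 and 5999, scaling to the median of detected probes 5085 and 5541, the deposited values 5267 and 5379, the mean of a gene's probes 5218 and 5463, trend and robust 5398 and 5573, a 2-fold threshold 3698 and 3883, and an adjusted p under 0.01 3652 and 3752. Leaving out 1 array gave 7651 to 10053 calls, 3742 to 4912 higher and 3816 to 5184 lower in adult hepatocytes. The filter on saturated probes removed no probe and a slide or scan block was not possible, so neither gave a value.

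Lists past the threshold with all settings as planned that missed it under normexp correction were liver transcription factors 0.086, gluconeogenesis and liver-type sugar metabolism 0.086, mitochondrial respiratory chain 0.0547 and pericentral zone genes 0.0907. Under quantile normalization these were mitochondrial respiratory chain 0.712 and pericentral zone genes 0.114, and under both together mitochondrial respiratory chain 0.758 and pericentral zone genes 0.0791. Spike-in scaling lost mitochondrial respiratory chain 0.672, erythroid markers 0.164 and haematopoietic progenitor and megakaryocyte markers 0.174, and brought female-biased liver genes 0.00139 and endothelial markers 0.0252 past it. Without the filter on dim probes liver transcription factors 0.266, gluconeogenesis and liver-type sugar metabolism 0.309, mitochondrial respiratory chain 0.058, pericentral zone genes 0.309 and lymphocyte and antigen presentation markers 0.142 missed it and immediate early and heat shock genes 0.00964 passed. With probes detected on all arrays gluconeogenesis and liver-type sugar metabolism 0.124, pericentral zone genes 0.416, erythroid markers 0.0802, haematopoietic progenitor and megakaryocyte markers 0.727 and lymphocyte and antigen presentation markers 0.205 missed it and female-biased liver genes 0.0228 passed. At an adjusted p under 0.01, gluconeogenesis and liver-type sugar metabolism 0.0229, pericentral zone genes 0.0283, haematopoietic progenitor and megakaryocyte markers 0.0117 and lymphocyte and antigen presentation markers 0.0228 fell short. Fry gave erythroid markers 0.0698 and, in the opposite direction, female-biased liver genes 0.0455. Leaving out arrays, endothelial markers ranged from 0.021 (without E13 replicate 1) to 0.67 (without adult replicate 2) and pericentral zone genes from 0.0143 (without E13 replicate 2) to 0.079 (without adult replicate 2).

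Median log2 folds of the lists ranged over the settings other than spike-in scaling as follows: hepatoblast and oncofetal genes -7.94 to -2.67, imprinted genes -7.02 to -3.41, liver transcription factors 0.38 to 0.79, secreted plasma proteins 0.88 to 1.99, coagulation and complement factors 1.52 to 2.19, cytochrome P450s of drug metabolism 5.33 to 7.59, conjugation enzymes 3.63 to 4.83, bile acid synthesis and transport 3.54 to 5.87, urea cycle and amino acid catabolism 2.96 to 3.50, gluconeogenesis and liver-type sugar metabolism 0.73 to 1.51, glycolysis genes with non-liver isoforms -1.34 to -0.60, fatty acid oxidation and ketogenesis 1.08 to 1.45, cholesterol synthesis -2.71 to -2.42, mitochondrial respiratory chain -0.023 to 0.57, mitosis genes -6.53 to -3.91, DNA replication genes -3.48 to -2.72, DNA methylation and chromatin regulators -1.52 to -0.98, pericentral zone genes 0.45 to 0.74, periportal zone genes 5.46 to 6.62, male-biased liver genes 5.59 to 8.57, female-biased liver genes 1.18 to 5.36, acute phase genes 4.25 to 6.60, immediate early and heat shock genes -0.73 to 0.35, cholangiocyte markers 0.0053 to 0.69, erythroid markers -3.93 to -1.15, haematopoietic progenitor and megakaryocyte markers -3.56 to 0.0078, macrophage and Kupffer cell markers 0.95 to 2.99, endothelial markers 0.54 to 2.24, stellate and mesenchymal markers -3.93 to -1.91, mesothelial markers -2.08 to 0.18, lymphocyte and antigen presentation markers 0.87 to 2.07. With a correlation estimated for each list, camera placed no list past the threshold. This held for lists estimated far above the preset 0.01 (erythroid 0.83, coagulation 0.593) and below it (imprinted -0.0535, glycolysis -0.0444). The test then rests on 2 residual degrees of freedom, so it cannot show whether correlation accounts for a list's call. The adjusted p was 0.302 for hepatoblast and oncofetal genes, imprinted genes, liver transcription factors, secreted plasma proteins, cytochrome P450s of drug metabolism, conjugation enzymes, bile acid synthesis and transport, urea cycle and amino acid catabolism, glycolysis genes with non-liver isoforms, cholesterol synthesis, mitosis genes, DNA replication genes, DNA methylation and chromatin regulators, male-biased liver genes, acute phase genes and lymphocyte and antigen presentation markers. Others that missed it were coagulation and complement factors at 0.409, gluconeogenesis and liver-type sugar metabolism and pericentral zone genes at 0.442, fatty acid oxidation and ketogenesis and stellate and mesenchymal markers at 0.458, mitochondrial respiratory chain at 0.449, periportal zone genes at 0.377, erythroid markers and haematopoietic progenitor and megakaryocyte markers at 0.534 and macrophage and Kupffer cell markers at 0.475.

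Among named genes called under either setting the direction reversed under normexp correction for Kit 0.53 and Wt1 0.058, under quantile normalization for Alb -0.24 and Mthfd1 -0.0086, and under both together for Alb -0.23 and Ndufs1 -0.35. Spike-in scaling moves every log2 fold by the same -1.23, so every positive fold below that size turns negative by the shift alone. Of these, called under either scaling were Alb -0.18, Cd68 -1.002, Gldc -1.16, Glul -0.79, Gstt1 -0.93, Hnf4a -0.29, Krt19 -1.14, Met -0.85, Mthfd1 -0.59, Ndufs1 -0.87, Ndufv2 -1.11, Pfkm -0.82, Pfkp -1.12, Serpind1 -0.83, Shmt1 -0.95, Shmt2 -0.48, Tagln -1.02 and Ugt2b34 -1.04, and under neither Slc2a2 -0.17, Stat3 -0.55, Cyp17a1 -0.56 and Fos -1.20. Anln turned to 0.74 without adult replicate 2 and lay at -4.79 without adult replicate 1.

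With the replicate number as a block, 9495 genes were called, 4666 higher and 4829 lower in adult hepatocytes. A crossed pairing, added after the data were examined, gave 10768, with 5336 higher and 5432 lower. The differences between replicates 1 and 2 in the groups correlated at -0.156 across 16421 genes.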

Other observations

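The tests of this part, and the serine, Bex, growth factor, isozyme and sex chromosome groups, were chosen after the values were seen, while the cell type and liver lists had been set before. Of 8 serine and one-carbon enzymes measured, 5 were called higher in E13 hepatoblasts, 2 higher in adult hepatocytes and 1 neither. Phgdh (at least 2518-fold), Psat1 (at least 439.7-fold) and Psph (23.7-fold), the enzymes that make serine from a glycolytic intermediate, and the mitochondrial folate enzymes Mthfd1l (65.4-fold) and Mthfd2 (30.6-fold, well above background on 1 adult array) were higher in E13 hepatoblasts. Shmt2 (1.68-fold) and Mthfd1 (1.56-fold) were called slightly higher in adult hepatocytes, but turned to -0.48 and -0.59 under spike-in scaling, and Shmt1 was at 0.28 ± 0.16 (-0.95). The Shmt2 call was lost without E13 replicate 1, adult replicate 1 or adult replicate 2 (limma adjusted p = 0.0938, 0.0554 and 0.0525; 0.00419 to 0.441 over the alternatives). The Mthfd1 call was lost without E13 replicate 1, E13 replicate 2 or adult replicate 2 (limma adjusted p = 0.0637, 0.152 and 0.0956; 0.00869 to 0.966 over the alternatives). The 4 measured Bex genes, small adaptor proteins, were all called higher in E13 hepatoblasts, Bex1 (at least 1177-fold), Bex2 (at least 1496-fold), Bex4 (2589-fold, well above background on 1 adult array) and Ngfrap1 (now Bex3; 525-fold). Leaving out either adult array moved the log2 value of Mthfd1l (-6.65 to -5.41) and Bex4 (-12.40 to -10.28).

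Of 10 genes of the insulin-like growth factor axis, 5 were called higher in adult hepatocytes, 4 higher in E13 hepatoblasts and 1 neither. Igf2 (at least 5583-fold) and its receptor Igf2r (10.6-fold) were higher in E13 hepatoblasts, while Igf1 (1857-fold), the growth hormone receptor Ghr (8.45-fold), Igfbp2 (45.6-fold) and Igfals (7.73-fold), whose product carries Igf1 in blood, were higher in adult hepatocytes. Igf1r (at least 2.27-fold) and Igfbp3 (at least 5.74-fold) were higher in E13 hepatoblasts. The Igf1r call was lost without E13 replicate 1, E13 replicate 2 or adult replicate 2 (limma adjusted p = 0.124, 0.0547 and 0.0619; 0.00166 to 0.124 over the alternatives), and the Igfbp3 call without adult replicate 1 (0.0654; 0.00102 to 0.0654 over the alternatives). Igfbp1 was at -1.10 ± 0.60 and was called without adult replicate 1 (-1.96). Of 6 isozymes of 3 reactions, picked for their values and put to no list test, 2 were called higher in adult hepatocytes and 4 higher in E13 hepatoblasts. The desaturase Scd1 was higher in adult hepatocytes (23.4-fold) and Scd2 in E13 hepatoblasts (695-fold), and the acetate-activating enzyme Acss2 in adult hepatocytes (3.7-fold, missing the threshold at 0.65 under spike-in scaling) and Acss1 in E13 hepatoblasts (at least 467-fold). The hexokinases Hkdc1 (at least 221-fold) and Hk2 (at least 15.2-fold) were both higher in E13 hepatoblasts. The log2 value of Igfbp3 (bound 1.69 to 3.35) moved on leaving out either E13 array.

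Markers of other cell types were higher on E13 replicate 1 than on E13 replicate 2. The list medians differed by 1.87 (erythroid), 1.25 (endothelial), 1.21 (stellate), 0.91 (macrophage) and 0.89 (progenitor and megakaryocyte), and Hbb-b1, an abundant red cell gene, was at 7.04 and 5.01. RNA from other cells in differing shares in the E13 samples stays open as an explanation, since the count of 5 of these 5 lists above the bound of random lists restates the pattern and does not test it. A difference in scaling was argued against by the hepatoblast list, which differed by -0.164, the other way and below its random range (-0.113 to 0.081). Plasma (0.16), coagulation (0.41) and P450 genes (0.43), though, also lay above their bounds. Whether the erythroid, stellate and macrophage differences between the groups came from purity or from development was not tested, since the design varies both together.

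Most genes were lower in adult hepatocytes when the arrays were scaled to spike-in RNA (median -1.24). Less labelled RNA relative to spike-in RNA on the adult arrays could not be settled, with the log2 summed signal over spike-in signal differing by -0.595, short of the median gene's shift. The 100 brightest spots held 34.3 and 32.6% of the signal on the adult arrays against 25.4 and 27% on the E13 arrays. Leaving them out moved the difference to -0.744, towards that shift but short of it, which argues against them only as the whole cause. The RNA content of the cells was not tested.

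Xist, the RNA that silences an X chromosome in females, was higher in E13 hepatoblasts (at least 91.7-fold), and the Y-linked genes Ddx3y (4.01-fold), Eif2s3y (5.92-fold), Kdm5d (3-fold) and Uty (6.36-fold, well above background on 1 E13 array) were higher in adult hepatocytes, Eif2s3y by a log2 fold of 1.96 to 3.17 and Uty by 2.05 to 3.29 on leaving out either E13 array. All 3 Xist probes were well above background on both E13 arrays and on 0 adult arrays. Between the E13 arrays the 4 Y-linked genes differed by 1.12 (median) and Xist by -0.626, which compares the E13 samples only. The 4 Y-linked genes were well above background on both adult arrays. The adult arrays thus showed Y-linked RNA without detected Xist, and the E13 arrays showed both. Differing shares of male and female cells may account for the difference between the groups. Scaling did not remove it, the lowest Y-linked median being 1.05 and the Xist value nearest 0 being -4.91, although Kdm5d and Ddx3y missed the threshold under spike-in scaling and Kdm5d without adult replicate 1 (limma adjusted p = 0.0644) or 2 (0.0747; 0.000701 to 0.442 over the alternatives). The labels give no sex, and the sex-biased liver genes of the adult hepatocytes are confounded with age here.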
